A study of Mus musculus with 41 samples.

How the data were processed

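The series holds 41 samples from female BALB/cJ mice, 28 measured by droplet-based single-cell RNA sequencing and 13 by bulk RNA sequencing of cultured cells. The single-cell samples came from the Peyer's patches and the lamina propria of the small intestine of 10-week-old mice, either untreated controls or mice in which inflammation had been provoked with ovalbumin, which the labels call food allergy. The bulk samples were KLRG1+ group 2 innate lymphoid cells (ILC2s) of 8-week-old mice, sorted at 250 cells per culture and kept for 3 hours in medium with IL-2 and IL-7 at 100 ng/ml each. IL-25 at 100 ng/ml, α-CGRP at 0.4 μg/ml, both or neither were added, which gave 4 groups.

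For the bulk samples the deposited values were expected counts per gene, estimated read counts that need not be whole and were not scaled to depth. Per the submitters' processing notes the tools of the series were bcl2fastq, Bowtie2, RSEM and Cell Ranger with genome build mm10, and versions, annotation and parameters were not given in the sources used here. The labels name the Smart-seq2 protocol for these libraries, which reads whole transcripts without molecular identifiers, so intervals and floors given for them cover counting error only. For the single cells the deposited values were raw counts of unique molecular identifiers (UMIs) per gene and cell, with 1 list of gene symbols and 1 list of cell names, and each cell name carried the title of its sample. The matrix held 58067 cells, 30723 of controls and 27344 of food allergy, and 19221 genes, and these cell numbers equal those in the series' design text. The lowest total of a cell was 501 UMIs and the highest share of mitochondrial UMIs was 13.4%, so the authors' matrix had been filtered on both. Of the 28 single-cell samples 27 had cells in the matrix, and the food allergy library of Peyer's patches numbered 1 was not analysed here. No per-sample column of the deposited tables was left unused.

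Bulk expected counts were rounded to whole numbers. Genes with enough counts by edgeR's filterByExpr were kept, 12355 of 23420, and libraries were scaled by trimmed mean of M-values (TMM) factors. All 13 libraries entered 1 model with a mean per group, and each contrast was tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. The contrasts were IL-25 against base medium, CGRP against base medium, CGRP with IL-25 against IL-25, IL-25 with CGRP against CGRP, and the interaction of both. Levels are TMM-scaled counts-per-million values (CPM) with their SD over libraries. All bulk adjusted p-values below come from this test unless another tool is named. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. A total of 24 gene lists fixed before the data were examined were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry.

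Cells were clustered from the raw counts after scaling each cell to 10000 counts and taking logarithms. The 2500 genes with the highest variance of Pearson residuals, without immunoglobulin, T cell receptor segment, ribosomal and mitochondrial genes, gave 40 principal components, 20 neighbours per cell and 50 Leiden clusters at a resolution of 1.5 (leidenalg 0.10.2, python-igraph 0.11.9). A cluster took a name only from markers fixed before the data were examined and only if at least 3 of them stood out and no other class had more markers among its 10 leading genes. In all 39 clusters were named, forming 22 classes, and 11 clusters with 4032 cells (6.94%) stayed unnamed. The names are rebuilt from the counts, so a class called ILC2-like here need not hold the same cells as the authors' class. Doublets were called by simulating pairs of cells within each library at 0.8% per 1000 cells, which marked 1170 cells (2.01%), and these were kept except in an alternative.

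UMI counts were summed per class and sample and tested across samples with edgeR's quasi-likelihood test, with run date as a covariate. In the lamina propria the unit was the library, 3 of controls and 3 of food allergy on 2 run dates, from the sort that the labels call nonTB, a term they do not define. Whether lamina propria libraries of the same date and condition came from separate animals is not stated. Their p-values thus measure the spread between these libraries, which may be technical. In Peyer's patches the unit was the sum of all libraries of 1 run date and condition, since libraries of a date may come from the same animals, with at least 10 cells per sum. Single-cell adjusted p-values below come from this test within each class unless another tool is named. Shares of cells per class were compared by an exact permutation of condition within run date and, where given, within position, two-sided, with Benjamini-Hochberg adjustment over classes that held at least 20 cells. A further pair of lamina propria libraries, whose sort the labels call IgDLow, had 1 library per condition and gave values only, with exact Poisson and Clopper-Pearson intervals at 95%. For a group with no count, a ratio was computed against a floor of 3 counts over the group.

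Named genes were taken by a rule fixed before the data were examined. In each bulk contrast it took the 10 largest rises and the 10 largest falls among genes past 0.05 whose libraries did not overlap, the leading members of each list, and 17 genes in every contrast. In single cells it took, for the ILC2-like class and the classes with the most changed genes, the 5 largest rises and falls with the same sign on every run date and the list members past 0.05. Predicted genes and pseudogenes were counted but not named. Gene positions come from the GENCODE M21 annotation of GRCm38, the assembly of build mm10, matched by symbol, and were not used in any test. The report gives the part of these genes with the clearest values, and summarises the others. The genes Mcpt1, Mcpt2, Cpa3, Cma1, Hspa1a, Txnip, Lmna and Ighg1 across all classes, and Il6, Il17a and Pdcd1 in ILC2-like cells, were added after their values were seen. The test of tissue by condition in ILC2-like cells, the minimum of 20 cells for shares, the contrasts averaged over both bulk arms, and the clusters singled out in the IgDLow libraries were also chosen after the data were seen.

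Alternatives fixed beforehand were DESeq2 1.42.0, size factors by relative log expression, no filter on low counts, the replicate number as a block, fits on the compared groups alone, leaving out each library or run date, no run date term, 25 cells per sum, a filter at 1000 UMIs and 10% mitochondrial UMIs, removal of doublets, and doubled clustering resolution. Fits without the ribosomal RNA gene Rn45s, without a Peyer's patch control library that had no partner, and with clusters made without any marker or list gene, and edgeR's test of lamina propria shares without each library, were added after seeing the data. Levels of CGRP genes in ILC2-like cells were tested against the average of the other classes' fitted log2 levels, and their ratio to the plain mean of those classes is given beside the test. The scripts were tested on simulated counts drawn from the real means and depths. At the adjusted threshold they recovered 69.1% of genes changed 4-fold in the CGRP contrast (11873 genes) and 9% of those changed 2-fold, and 53.1% and 8.33% in the IL-25 contrast (11781 genes). For ILC2-like cells they recovered 97.7% and 73.9% in the lamina propria (3713 genes) and 83.3% and 45.7% in Peyer's patches (5528 genes). The interaction contrast recovered 30.1% of 4-fold and 1.03% of 2-fold changes (11758 genes). Figures were drawn with matplotlib 3.10.9.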

Results

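Immune cells of the mouse small intestine were profiled by single-cell RNA sequencing in control mice and in mice with ovalbumin-provoked food allergy, to ask which cell types and genes differ in the allergic gut. The lamina propria, the connective tissue beneath the gut epithelium, gave 3 control and 3 food allergy libraries of the nonTB sort, with 2285 to 2822 cells each and a median of 1829 to 3442 UMIs per cell. Peyer's patches, the lymphoid follicles of the gut wall, gave 10 control and 9 food allergy libraries over 5 run dates, with 379 to 3891 cells each and medians of 2682 to 3975 UMIs. In a second experiment, sorted KLRG1+ ILC2s, tissue-resident lymphocytes that secrete type 2 cytokines, were cultured with IL-25, an epithelial cytokine that activates ILC2s, with α-CGRP, a neuropeptide encoded by Calca, with both or with neither. The bulk groups held 3 base medium, 3 IL-25, 4 CGRP and 3 combined libraries, with totals of 6942739 to 21551863 expected counts. The ribosomal RNA gene Rn45s took 57.5% to 78.7% of these totals and did not differ past the threshold in any contrast (lowest adjusted p = 0.678). Gene positions are those of GENCODE M21 on build mm10.

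Mast cells, the granulocytes armed by IgE, made up 9.49% ± 1.75 of lamina propria nonTB cells in food allergy and 0.747% ± 0.239 in controls (SD, n = 3 each), a 12.7-fold ratio. Neutrophil-like cells stood at 1.34% ± 0.233 against 0.148% ± 0.0981, and B cell-like cells at 2.89% ± 3.56 against 0.205% ± 0.283. Food allergy library 3 held 6.99% B cell-like cells and the other 2 held 0.786% and 0.886%, so that the mean was 0.836% without it, and the control mean was 0.0438% without control library 3. Classical dendritic cells of type 2 (cDC2-like) were at 1.71% ± 0.243 in food allergy against 4.85% ± 0.233 in controls. Plasmacytoid dendritic cells (pDC-like), the main producers of type I interferon, were at 6.10% ± 2.12 against 14% ± 3.96, and stromal-like cells at 0.0711% ± 0.0709 against 0.904% ± 0.307, on 6 and 66 cells (0.0357% without food allergy library 2). The ILC2-like, ILC3-like and plasma cell-like shares were 7.68% ± 1.56, 29.1% ± 0.396 and 23.1% ± 2.41 in food allergy and 7.04% ± 2.34, 28.8% ± 3.47 and 22.4% ± 0.427 in controls. With 12 arrangements of condition within run dates the exact two-sided permutation test cannot give a p below 0.167, which mast cells, neutrophils, B cells, cDC2s, pDCs, monocytes and stromal cells all reached, and 0 of 15 classes passed at 0.05. EdgeR's test of the same cell numbers put 7 of these classes past 0.05, with germinal centre B cells in place of monocytes. Of 27 germinal centre B cell-like cells, all from food allergy, 26 lay in library 3, and the call was lost without that library or control library 3 (adjusted p = 0.439 each), where monocytes passed (0.00252 each). There cDC1-like cells passed too (adjusted p = 0.0456 each), and their log2 ratio turned from -0.196 with all libraries to 0.414. Among the 7 classes called with all libraries were mast cells (log2 3.66 ± 0.32 SE, adjusted p = 7.08e-08), cDC2s (log2 -1.50 ± 0.26, adjusted p = 9.15e-05) and pDCs (log2 -1.21 ± 0.31, adjusted p = 0.00286). With clusters made without any marker or list gene, an alternative chosen after seeing the data, edgeR's log2 ratio was 3.65 for mast cells and -1.21 for pDCs, and no cDC2 class was formed. The nonTB sort sets which cells could be counted, and shares of a total move together.

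**Figure D1:**
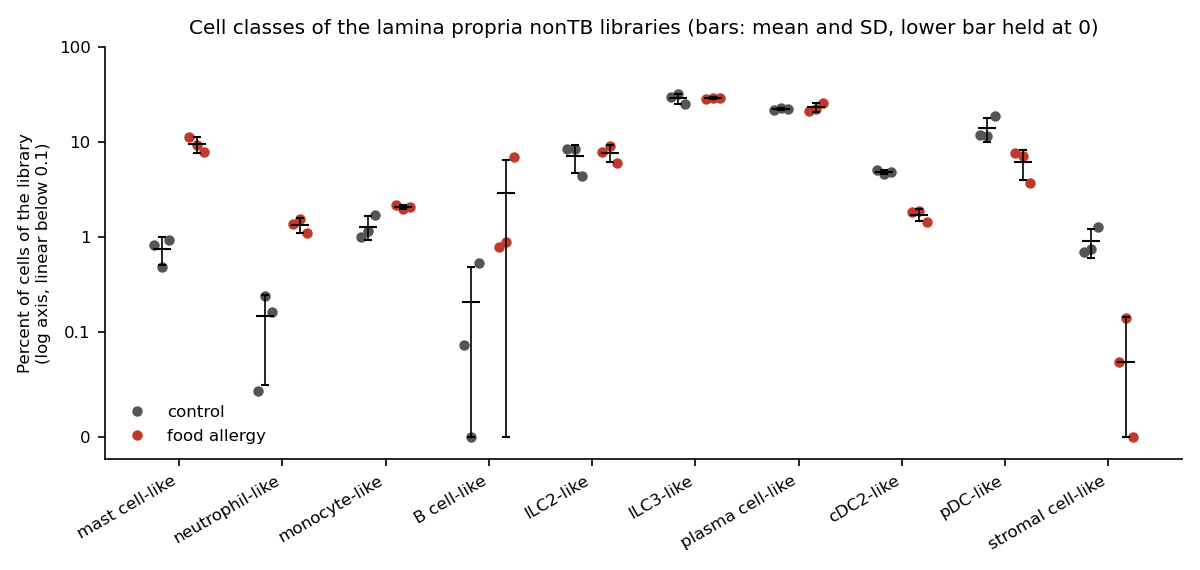
Share of cells per class in the lamina propria nonTB libraries (vertical axis, percent of cells), controls beside food allergy. The axis is logarithmic and linear below 0.1%, points are libraries, horizontal marks group means and error bars the SD over 3 libraries, with lower bars held at 0; the mast cell mean was 0.747% in controls and 9.49% in food allergy, and the cDC2 mean 4.85% and 1.71%.

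ILC2-like cells of the lamina propria carried far more type 2 cytokine mRNA in food allergy than in controls (510 control and 621 allergy cells, 3 libraries each). Il13, the cytokine that drives mucus and smooth muscle responses (chromosome 11, 53631324 to 53634702), rose from 91.7 ± 35.2 to 1404 ± 482 CPM, 14.5-fold (adjusted p = 1.05e-09). Il5, the eosinophil growth factor encoded beside it (chromosome 11, 53720794 to 53725106), rose from 7.66 ± 13.3 to 338 ± 147 CPM, on 5 and 312 UMIs (adjusted p = 1.49e-07). Areg, an epidermal growth factor receptor ligand active in tissue repair, rose 4.11-fold to 1294 ± 485 CPM and Ccl1, a chemokine, 4.82-fold to 733 ± 358 CPM. Csf2, which encodes GM-CSF, rose 8.23-fold and Il4 3.44-fold (adjusted p = 0.00016 and 0.00125), each higher on 1 of 2 run dates. Of 9 measured type 2 cytokines and ILC2 products 6 rose and 1, Il2, fell (7 and 1 adjusted over the list alone). Calca, which encodes α-CGRP (chromosome 7, 114631478 to 114636357), was among the genes at high level in this class, at 1924 ± 415 CPM in controls and 2372 ± 368 in food allergy (adjusted p = 0.107). Il17rb, the IL-25 receptor, and the lineage factor Gata3 were also not past the threshold (adjusted p = 0.0538 and 0.0582). Calca, Il13, Il5, Areg, Ccl1, Il4, Il17rb and Gata3 were markers used to name the class, and 99.1% of its cells kept the name when clusters were made without any marker or list gene.

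The receptor subunit Ramp3 (chromosome 11, 6658521 to 6677475), which pairs with the CGRP and adrenomedullin receptor Calcrl, rose 2.44-fold in these ILC2-like cells, from 362 ± 156 to 843 ± 158 CPM (adjusted p = 0.000245). Ramp1 (chromosome 1, 91179822 to 91225196), the subunit of the high-affinity CGRP receptor, fell from 181 ± 18.7 to 115 ± 38.6 CPM (adjusted p = 0.0179). Of 5 measured neuropeptide and neurotransmitter receptor genes 3 rose and 1 fell, by both adjustments. Pdcd1, which encodes the inhibitory receptor PD-1, rose 12.7-fold from 18.3 ± 12.3 to 246 ± 68.1 CPM (adjusted p = 2.4e-08) and the costimulatory receptor Tnfrsf9 4.68-fold, so that 3 of 9 costimulatory and inhibitory genes rose (4 adjusted over the list alone). The chemokine receptor Cxcr6 rose 3.54-fold (adjusted p = 1.01e-08). Immediate early and cAMP-responsive genes split, with 10 of 25 up and 9 down (11 and 9 adjusted over the list alone). Nr4a3 rose 6.54-fold, Crem 2.43-fold and Fosl2 2.88-fold, and Nab2, a partner of Egr factors, 23-fold. Fos fell 2.70-fold from 4246 ± 1180 CPM (adjusted p = 2.4e-08), Dusp1 2.28-fold, Ppp1r15a 3.49-fold, Jun 1.72-fold and Ier2 1.51-fold. Heat shock genes rose in 6 of 8 cases by both adjustments, Hspa8 2.15-fold and Hsp90aa1 1.84-fold.

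Transcripts almost absent from control ILC2-like cells included Hspa1a, an inducible heat shock protein, with 1 control and 201 allergy UMIs (ratio 163, counting interval 28.9 to 6470). Others were the cytotoxic granule gene Gzmb with 3 and 105 (ratio 28.4, 9.45 to 140), Dusp2 with 3 and 80 (ratio 21.6, 7.14 to 107) and Egr2 with 3 and 47 (ratio 12.7, 4.09 to 63.8). Esm1 fell 14.3-fold, Bmp2 11.2-fold, the nuclear lamina gene Lmna 5.96-fold and Il2 3.27-fold, whereas the IL-2 receptor chain Il2rb rose 2.20-fold. The mast cell protease Mcpt1 was at 0 and 35 UMIs, at least 9.46-fold higher in food allergy, and 5 of 10 mitochondrial and nuclear RNAs that mark RNA quality rose with these genes (7 adjusted over the list alone). In all, 660 of 4098 genes passed 0.05 in this class, 408 higher and 252 lower. DESeq2 called 213, without Il4, Csf2, Crem and Ramp1 (adjusted p = 0.301, 0.206, 0.14 and 0.255), and Crem and Ramp1 were also lost without the run date term (0.0535 and 0.0757). Il17rb passed with cells of at least 1000 UMIs (adjusted p = 0.0417) or with doublets removed (0.0464), and Calca without a filter on low counts (0.00912). The edgeR count was 359 without food allergy library 1, 433 without food allergy library 2 and 330 without control library 2.

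Leaving out single libraries ended a few of these ILC2-like calls. Crem lost its call without food allergy library 1 or control library 2 (adjusted p = 0.0597 and 0.0747). Ramp1 lost it without food allergy library 1, food allergy library 2, control library 1 or control library 2 (adjusted p = 0.0813, 0.103, 0.0588 and 0.0748), and Il4 without control library 2 (0.0914). All 5 control UMIs of Il5 lay in control library 3. Its log2 change, 5.72 ± 0.49, was 5.01 without control library 1 and 4.86 without control library 2, and without control library 3 or food allergy library 3 the run date with both conditions held 0 control and 266 allergy UMIs, at least 72.2-fold higher. Without food allergy library 3 or control library 3, the pair of the second run date, log2 changes were 3.30 for Nr4a3 and 2.53 for Il4 in both fits, and 2.03 and 2.02 for Crem. Hspa1a then had 1 control and 93 allergy UMIs (ratio 75.7, counting interval 13.3 to 3023) and Bmp2 38 and 2 (allergy to control ratio 0.0429, 0.00501 to 0.166). With 0 control UMIs left, Hspa1a was at least 33.8-fold higher without control library 2 and Gzmb at least 19-fold without control library 1, and without control library 2 the ratio of Gzmb was 17.6 (5.87 to 86.9). The log2 change was 1.85 for Csf2 and -2.51 for Il2 without food allergy library 2, and Esm1 had 122 control and 3 allergy UMIs without food allergy library 1 (allergy to control ratio 0.0287, 0.00584 to 0.0858).

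**Figure D2:**
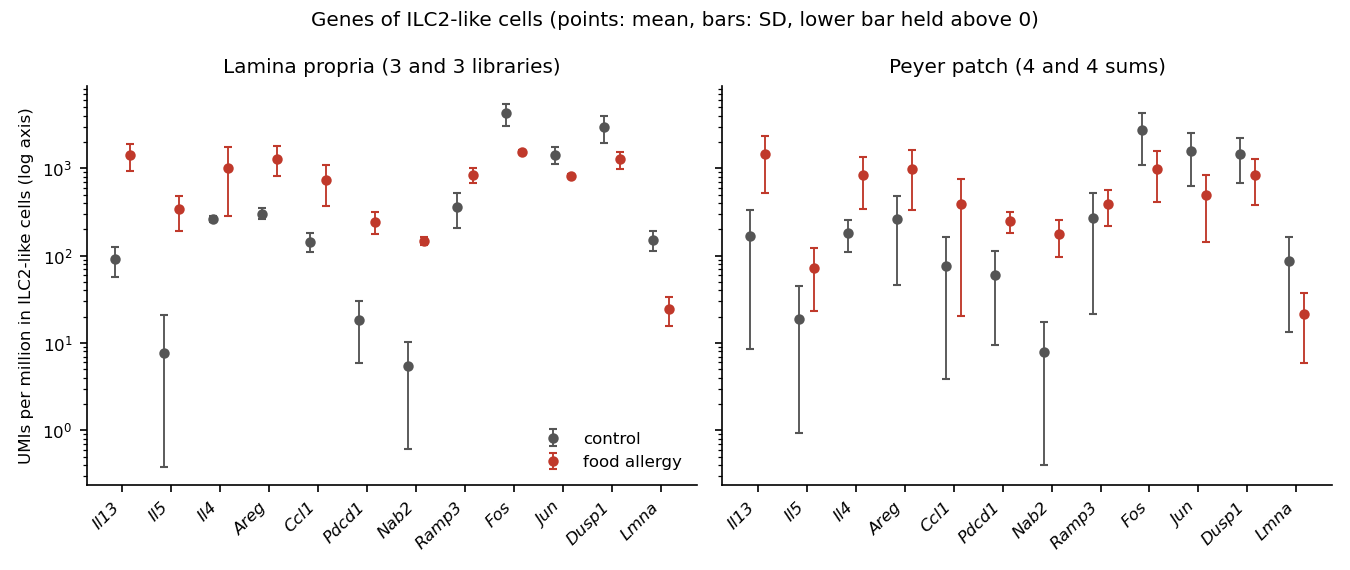
Level of 12 genes in ILC2-like cells (vertical log axis, UMIs in CPM) of the lamina propria, from 3 libraries per group, and of Peyer's patches, from 4 sums per group. Points are means and bars the SD, with lower bars held above 0; Il13 lay at 91.7 and 1404 in controls and food allergy of the lamina propria and at 169 and 1447 in Peyer's patches.

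Plasma cell-like cells of the lamina propria carried more Ighg1, the IgG1 heavy chain constant region (chromosome 12, 113325240 to 113330523), in food allergy, 1271 ± 798 against 203 ± 77.5 CPM (5.80-fold, adjusted p = 4.78e-05, 3 libraries each). The λ light chain regions Iglc1 and Iglc3 fell 2.60-fold and 3.97-fold (adjusted p = 0.0119 and 0.00313). They belong to a family with similar copies, whose reads may not be parted with certainty. Of the 12 listed immunoglobulin constant regions, which do not include Iglc3, 1 rose and 2 fell (3 and 4 adjusted over the list alone). Of 24 cell cycle genes 11 rose (16 adjusted over the list alone), with Ccnb1 up 3.07-fold, Ccna2 2.98-fold and Mki67 2.19-fold, and 5 of 12 glycolysis genes rose by both adjustments. Interferon response genes were lower in 3 of 9 cases (5 adjusted over the list alone), among them Irf7, which fell 2.06-fold. Hspa1a rose 3.26-fold. Mast cell genes were higher in these plasma cell-like cells in 6 of 7 cases by both adjustments, with Mcpt1 at 27.5 against 1.34 CPM, Mcpt2 at 15.5 against 0.391, Cma1 at 5.62 against 0.218 and Cpa3 at 10.4 against 0.551. The class had 249 genes higher and 87 lower past 0.05, and DESeq2 called 182. Without the run date term Iglc1, Ccnb1, Ccna2, Mki67 and Hspa1a were not past 0.05 (adjusted p = 0.241, 0.0731, 0.105, 0.167 and 0.273). Iglc1 lost its call without control library 2 (adjusted p = 0.0601) and Mki67 without food allergy library 1 or food allergy library 3 (0.108 and 0.0505), and Mcpt2 had 2 control and 302 allergy UMIs without control library 1 (ratio 89.7, counting interval 24.6 to 744).

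Mast cell-like cells, 54 in controls and 766 in food allergy, differed in their protease content, the proteases being markers that named the class. Tpsb2, a tryptase, had 3 control and 4487 allergy UMIs (ratio 88.8, counting interval 30.4 to 431). The chymase Cma1 rose from 553 ± 444 to 4981 ± 492 CPM (9.79-fold, adjusted p = 1.62e-05), Mcpt2 4.66-fold, Mcpt1 2.39-fold and Cpa3 2.86-fold, and the IgE receptor chain Fcer1a 2.51-fold, so that 9 of 12 mast cell genes rose by both adjustments. The cytokines Il6 and Tnf rose 4.11-fold and 5.79-fold, the IL-33 receptor Il1rl1 3.06-fold and Tph1, which starts serotonin synthesis, 8.31-fold, from 314 to 2529 CPM (adjusted p = 1.3e-06). Hspa1a had 0 control and 626 allergy UMIs, at least 12.4-fold higher (at least 5.14-fold without food allergy library 3). Sox4 fell 33.4-fold (adjusted p = 8.47e-08). B and plasma cell transcripts moved with these genes, 4 of 7 higher (5 adjusted over the list alone), with Igkc, the κ light chain, at 19800 against 2524 CPM. With doublets removed the log2 change of Igkc went from 2.81 to 0.71 (adjusted p = 0.115). In all 182 genes were higher and 43 lower (DESeq2 131), on as few as 12 control cells in a library. With no filter on low counts the genes named here as risen or fallen, Igkc included, had adjusted p-values of 0.234 to 0.61, and DESeq2 did not call Mcpt2 or Mcpt1 (adjusted p = 0.102 and 0.0723). Without the run date term Mcpt2, Mcpt1 and Il6 were not past 0.05 (adjusted p = 0.0507, 0.0783 and 0.112).

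Leaving out single libraries ended or moved several of these mast cell calls. Mcpt2 lost its call without food allergy libraries 1, 2 or 3 or control library 3 (adjusted p = 0.132, 0.137, 0.217 and 0.133), at 4.93-fold, 4.72-fold, 2.92-fold and 3.43-fold higher. Mcpt1 lost it without food allergy libraries 1, 2 or 3 or control libraries 2 or 3 (adjusted p = 0.0803, 0.0963, 0.102, 0.103 and 0.059), at 1.91-fold to 2.30-fold higher, and Fcer1a without food allergy library 1 or 2 (0.061 and 0.0533), at 2.15-fold and 2.13-fold. Log2 changes were 2.67 for Cma1, 3.72 for Mcpt2 and 2.85 for Il6 without control library 1, and 3.90 for Cma1 and -4.30 for Sox4 without control library 2. They were 3.97 for Cma1, 3.97 for Tph1 and 3.73 for Igkc without control library 3, and 3.69 for Tph1 and 3.42 for Igkc without food allergy library 3. The ratio of Tpsb2 was 54.7 (counting interval 18.7 to 265) without control library 1, and 167 on 1 control UMI (29.9 to 6579) without control library 3 or food allergy library 3.

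Over 10 lamina propria classes 1298 genes were called higher and 822 lower, each class counted on its own, and DESeq2 called 920. The count fell from 2120 to 942 without food allergy library 1, 1209 without food allergy library 2, 1218 without control library 1 and 976 without control library 2. ILC3-like cells had 69 genes higher and 129 lower, pDC-like cells 112 and 68, cDC2-like cells 80 and 78, cDC1-like cells 75 and 69, and NK cell or ILC1-like cells 16 and 20. Hspa1a rose in 7 of the 9 classes in which it was tested, Mcpt1 in 7 of 7, and the interferon regulator Irf7 fell in 7 of 9.

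In Peyer's patches ILC2-like cells of food allergy mice also carried more type 2 cytokine mRNA (4 control and 4 food allergy sums of run dates, 3 dates with both). Il13 rose from 169 ± 163 to 1447 ± 926 CPM, 7.96-fold within dates (adjusted p = 1.05e-20), and was higher on 3 of 3 dates. The p-values of this class rest on these 3 dates only. With the conditions exchanged on date 2 alone, 72 genes of the class were still called, against 157 with the real conditions. Exchanged on date 4 or date 5 alone, 0 were called. Il4 rose 4.68-fold (adjusted p = 4.08e-12), Il5 2.89-fold, Areg 3.31-fold and Ccl1 4.11-fold, and Il17a had 3 control and 71 allergy UMIs (ratio 14.6, counting interval 4.80 to 72.5). Of 11 measured type 2 cytokines and ILC2 products 7 rose, by both adjustments. Pdcd1 rose 2.66-fold, from 60.8 to 248 CPM (adjusted p = 1.91e-06), the adenosine receptor Adora2a 2.32-fold, Cxcr6 1.87-fold, Arg1, which encodes arginase, 1.86-fold and the kinase gene Plk3 8.44-fold, and Nab2 and Egr2 rose 7.15-fold and 5.87-fold. Of 25 cAMP and immediate early genes 2 rose and 9 fell (4 and 11 adjusted over the list alone), with Fos down 2.94-fold, Jun 2.28-fold, Ier2 2.56-fold, Egr1 2.72-fold and Dusp1 2.13-fold. Bmp2, Lmna and Txnip fell 4.80-fold, 4.66-fold and 3.05-fold. Calca stood at 924 CPM in controls and 1233 in food allergy (adjusted p = 0.956) and Gata3 at 1008 and 1555 (adjusted p = 0.326). The mast cell protease Mcpt1 was at 51.5 CPM against 11.6 in these cells, 4.30-fold higher (adjusted p = 9.68e-05). In all 100 genes were higher and 57 lower, and DESeq2 called 25, without Il5, Il4, Adora2a, Cxcr6 and Arg1 (adjusted p = 0.924, 0.0546, 0.165, 0.0603 and 0.42). Without the run date term 8 genes were called, and Il13, Il4, Il5, Areg, Ccl1, Pdcd1, Adora2a, Cxcr6, Arg1, Txnip, Fos, Jun, Ier2, Egr1 and Dusp1 were not past 0.05 (adjusted p = 0.105 to 0.691). Arg1 had an adjusted p of 0.0518 with clusters made without marker or list genes.

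Of 4023 genes tested in ILC2-like cells of both tissues, 117 were called in both, 115 of them in the same direction, where independent lists would share 12.4 in the same direction and 23.2 in either. ILC3-like cells of Peyer's patches had 29 genes higher and 89 lower (DESeq2 22), with 6 of 18 NF-κB response genes lower (14 lower and 1 higher adjusted over the list alone) and 7 of 27 cAMP and immediate early genes lower (15 adjusted over the list alone). The class was made up differently by condition: cluster 29, almost all of it from run date 4, held 13.8% of control and 1.65% of food allergy ILC3-like cells, and cluster 22 held 13% and 6.59%. Atf3 fell 2.08-fold, Rel 1.94-fold, the chemokine gene Cxcl2 3.52-fold and the hexokinase gene Hk2 2.37-fold, and Areg fell 2.33-fold, opposite to ILC2-like cells. DESeq2 did not call Mcpt1, Mcpt2, Areg, Atf3 or Rel there (adjusted p = 0.0996, 0.353, 0.373, 0.401 and 0.9999), and Areg was not past 0.05 with doublets removed (0.074) or with clusters made without marker or list genes (0.0544). NK cell or ILC1-like cells had 13 genes higher and 55 lower (DESeq2 13), with 8 of 18 NF-κB genes lower (12 adjusted over the list alone) and 7 of 25 cAMP and immediate early genes lower and 1 higher (15 and 1 adjusted over the list alone). Areg fell 5.01-fold, Nfkbid 2.86-fold and Rel 2.43-fold there, and Il22, a cytokine acting on epithelium, rose from 9.49 to 50.7 ± 76.2 CPM (adjusted p = 0.000243), higher on 3 of 5 dates. Txnip, a brake on glucose uptake, rose 3.12-fold in ILC3-like and 3.03-fold in NK cell or ILC1-like cells, each on 5 of 5 dates. Mcpt1 and Mcpt2 rose with them, 4.96-fold and 4.62-fold in ILC3-like cells. DESeq2 did not call Rel in NK cell or ILC1-like cells (adjusted p = 0.0981). Without the run date term Txnip in both classes, Areg, Hk2, Atf3 and Rel in ILC3-like cells and Nfkbid and Rel in NK cell or ILC1-like cells were not past 0.05 (lowest adjusted p = 0.248).

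Over 13 Peyer's patch classes 191 genes were called higher and 237 lower, 428 in all, and the 15 other ways to exchange the conditions within run dates called up to 572. DESeq2 called 69, with 37 and 32. Without run date 4 or 5 there were 10 classes that could be tested, not including ILC2-like cells, and these 10 held 264 of the 428 calls, 86 higher and 178 lower. They held 72, with 49 higher and 23 lower, without date 4 and 80, with 60 and 20, without date 5, and the 7 classes left without date 2 held 406 against 249 with all dates. ILC2-like cells could not be tested without date 2 either, so no call of that class was checked without date 2, 4 or 5. Without date 5 the ILC3-like calls of Mcpt1, Areg, Atf3 and Rel were lost (adjusted p = 0.24, 0.168, 0.24 and 0.254), with a log2 change of 1.31 for Mcpt1 and -1.93 for Areg. So were those of Nfkbid and Rel in NK cell or ILC1-like cells (adjusted p = 0.144 and 0.184). Without date 4 Atf3 and Rel were lost in ILC3-like cells (0.413 and 0.317) and Rel in NK cell or ILC1-like cells (0.154). Of the 5 dates, dates 1 to 3 held 84.7% to 87.0% T and B cells and dates 4 and 5 held 3.96% to 5.20%, so shares were compared within dates. ILC3-like cells were at 12.8% ± 16.7 in food allergy and 14.6% ± 18.4 in controls (9 and 10 libraries). The within-date ratio was 0.668 and lay below 1 on 5 of 5 dates (exact stratified permutation p = 0.0026, the smallest of 768 arrangements, adjusted p = 0.0573). That test takes libraries of a date as separate, although they may share animals. Over sums of the 5 dates, with 32 sign flips, a two-sided p cannot go below 2 of 32, so no share can pass 0.05 there. Within-date ratios were 1.24 for NK cell or ILC1-like cells, 2.55 for mast cell-like cells and 2.36 for monocyte-like cells (exact permutation, adjusted p = 0.0859 each). The exact test put 0 of 22 classes past 0.05 adjusted, against 5 at an unadjusted p under 0.05 and 2 by edgeR, mast cells (log2 1.69) and monocytes (log2 1.44). With clusters made without marker or list genes the monocyte log2 ratio was 0.78 and not past 0.05 (adjusted p = 0.134).

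CGRP genes were compared across lamina propria classes in the 3 control libraries, to ask which cells carry mRNA of the neuropeptide and of its receptor. Calca stood at 1744 ± 391 CPM in ILC2-like cells, on the scale of this fit across classes, 157-fold the mean of the 10 other classes. The next levels were 50 ± 30.6 CPM in mast cell-like cells, on 11 UMIs in 54 cells, 45.4 ± 11.6 in NK cell or ILC1-like and 7.82 ± 6.92 in ILC3-like cells. EdgeR compared ILC2-like cells with the average of the other classes' fitted log2 levels, which for Calca includes 3 classes at 0 UMIs and so gives no fold (adjusted p = 2.27e-53). Calca was also one of the markers that named this class. Ramp1 stood at 164 ± 18.4 CPM in ILC2-like, 120 ± 50.1 in ILC3-like and 480 ± 1.56 in pDC-like cells, and in ILC2-like cells was 1.93-fold the mean of the others (adjusted p = 1.4e-11 against their average log2 level). Ramp3 stood at 329 ± 145 CPM in ILC2-like, 208 ± 85.9 in ILC3-like and 7.92 ± 1.82 in pDC-like cells, and in ILC2-like cells was 9.02-fold the mean of the others, 1 of which was at 0 UMIs (adjusted p = 4.67e-31). Calcrl, the receptor's signalling subunit (chromosome 2, 84330626 to 84425411), had 5 UMIs in 510 ILC2-like cells, 5.09 ± 5.59 CPM, against 107 ± 44.1 CPM in stromal-like cells and a mean of 13.9 CPM over the others. In ILC2-like cells its level was 7.64 CPM without control library 1 and 2.10 without control library 2. Calcrl did not differ past the threshold from the other classes' average log2 level (adjusted p = 0.68), which includes 1 class at 0 UMIs and so gives no fold.

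**Figure D3:**
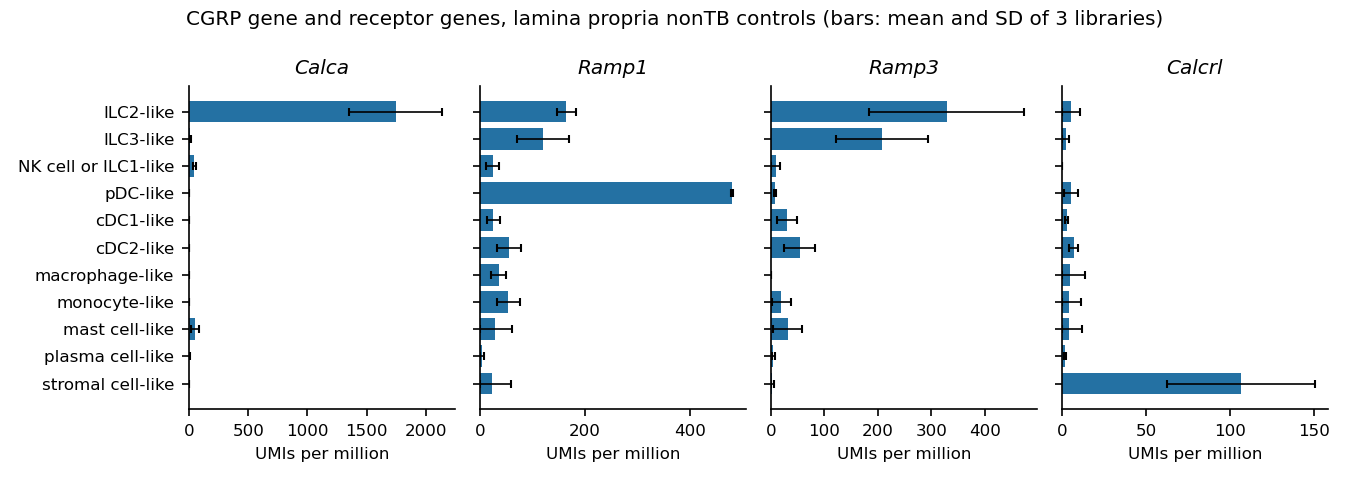
Level of Calca, Ramp1, Ramp3 and Calcrl (horizontal axes, UMIs in CPM) in 11 cell classes of the lamina propria nonTB controls. Bars are means and error bars the SD of 3 libraries, with lower bars held at 0; Calca was at 1744 in ILC2-like cells, Ramp1 at 480 in pDC-like cells and Calcrl at 107 in stromal-like cells.

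In cultured KLRG1+ ILC2s, IL-25 was compared with base medium to ask what the cytokine induces on its own within 3 hours. Il5 rose from 82.1 ± 1.80 to 389 ± 130 CPM (4.74-fold, adjusted p = 0.000642, 3 libraries each). Il13 rose from 6.30 ± 2.03 to 44 ± 12.8 CPM (6.96-fold, adjusted p = 0.00267) and Il9, a mast cell growth factor (chromosome 13, 56479277 to 56482246), from 33.1 ± 21.7 to 388 ± 145 CPM (11.8-fold, adjusted p = 0.00382). Csf2 rose 3.60-fold, the kinase gene Pim2 3.39-fold and Ptgs2, which encodes cyclooxygenase-2, 6.03-fold from 1.76 ± 1.08 CPM. Of 12 type 2 cytokines and ILC2 products 4 rose (6 adjusted over the list alone), and the list as a whole was higher (camera, adjusted p = 0.0225 with an estimated correlation). The NF-κB response list was also higher (adjusted p = 0.0225 with an estimated correlation), with 0 of 19 members past 0.05 over all genes and 2 adjusted over the list alone. Camera's call of the Myc and ribosome biogenesis list was lost (adjusted p = 0.0701 with an estimated correlation), as were those of T helper lineage genes and ILC3 and ILC1 markers (0.0723 and 0.14). Nr4a1 stood at 48.6 ± 20.7 and 120 ± 32.3 CPM (adjusted p = 0.197, DESeq2 0.0238), Bcl3 at 5.17 ± 1.15 and 14.7 ± 1.48 (adjusted p = 0.538). The IL-25 receptor gene Il17rb stood at 85.1 ± 9.99 and 55.3 ± 6.57, and Areg at 6.56 ± 1.62 and 4.74 ± 0.706. The 3 other genes that rose, Mmrn1, with 2 counts in base medium and 349 with IL-25 (ratio 141, counting interval 38.6 to 1166), Reln, from 0.257 to 9.37 CPM, and Sdpr, from 0.0912 to 10.4 CPM, are known from endothelium. The group means of 15 of 15 other endothelial markers were also higher with IL-25, such as Pecam1 at 45.2 against 22.1 CPM (adjusted p = 0.446, DESeq2 0.044). Of the 7 tested by edgeR 0 passed 0.05 (lowest adjusted p = 0.117), against 5 at an unadjusted p under 0.05 and 2 by DESeq2. Ccl21a, Plvap and Esam had no counts in IL-25 libraries 1 and 2, and 12 of 15 means were higher without IL-25 library 3.

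In all 9 genes rose with IL-25 and 0 fell (edgeR; 476 at an unadjusted p under 0.05, DESeq2 24). The count was 3 without base library 2, 4 without IL-25 library 1 and 6 without base library 3 or IL-25 library 2. Il5, Il13 and Il9 kept their calls in every such fit. Csf2 lost its call with RLE size factors (adjusted p = 0.063) and without base libraries 2 or 3 (0.444 and 0.442), IL-25 libraries 1 or 2 (0.153 and 0.519), CGRP libraries 1, 3 or 4 (0.0845, 0.0514 and 0.0722) and combined library 3 (0.0656), and Pim2 without base library 2 (0.0938). Ptgs2 lost its call without any 1 library other than CGRP libraries 2 and 3 (0.0522 to 0.211). Mmrn1 was lost without base libraries 2 or 3 or IL-25 library 1 (adjusted p = 0.0655, 0.0678 and 0.147). Reln was lost without those and IL-25 library 3 (adjusted p = 0.141, 0.151, 0.602 and 0.0739), and Sdpr without base libraries 1, 2 or 3 (0.143, 0.141 and 0.141) or IL-25 libraries 1, 2 or 3 (0.291, 0.0658 and 0.0745). The log2 change of Reln was 5.11, and 5.72 without base library 1. Sdpr had 1 base and 536 IL-25 counts without base library 3 (ratio 216, counting interval 38.6 to 8539).

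CGRP alone changed more genes, 134 higher and 50 lower against base medium (4 CGRP and 3 base libraries). Akap12, a scaffold of protein kinase A, rose from 4.07 ± 1.72 to 55.1 ± 8.69 CPM (13.9-fold, adjusted p = 1.21e-06), and Crem, a cAMP-induced repressor, from 110 ± 10.6 to 456 ± 28.8 CPM (4.13-fold, adjusted p = 2.4e-05). Of 29 cAMP and immediate early response genes 7 rose (15 adjusted over the list alone), and camera's call of the list was lost (adjusted p = 0.0645 with an estimated correlation). Among them the phosphatase gene Dusp10 rose 6.41-fold and Rgs2, a regulator of G protein signalling, 2.52-fold. The receptor genes Ramp3, from 102 ± 19.7 to 580 ± 58.3 CPM (5.71-fold, adjusted p = 2.4e-05), and Adora2a (2.90-fold) also rose. Of 18 costimulatory and inhibitory genes 4 rose by both adjustments (adjusted p = 0.138 with an estimated correlation), with Pdcd1 up 8.74-fold from 10.3 ± 2.72 CPM (adjusted p = 3.88e-06) and Tnfrsf9 3.85-fold. ILC2 identity genes rose in 3 of 20 cases and fell in 1 (7 and 1 adjusted over the list alone), and the list as a whole was higher (adjusted p = 0.0446 with an estimated correlation). Hs3st1 rose 4.76-fold and Gata3 2.05-fold from 343 ± 35.1 CPM, and the IL-2 receptor chain Il2ra fell 2.48-fold. Tgm2, a transglutaminase, rose 9.70-fold to 822 ± 168 CPM, Palld 11.8-fold and the chemokine receptor Ccr8 2.94-fold.

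Among cytokines, CGRP raised Il5 4.41-fold to 363 ± 85.9 CPM (adjusted p = 8.93e-05) and Areg 3.09-fold to 20.4 ± 5.29 CPM (adjusted p = 0.00763). Il13 stood at 6.30 ± 2.03 in base medium and 3.54 ± 1.72 CPM with CGRP (adjusted p = 0.328). Calca itself stood at 613 ± 99.8 and 1359 ± 473 CPM (adjusted p = 0.0524, DESeq2 0.00659) and Il17rb at 85.1 ± 9.99 and 151 ± 18.1 (adjusted p = 0.0634, DESeq2 0.00167). Ribosome biogenesis genes fell in 4 of 20 cases (11 adjusted over the list alone), and the list as a whole was lower (adjusted p = 0.0446 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, fell 3.82-fold from 17.1 ± 0.175 CPM, Rrp12 3.69-fold and Nop16 2.99-fold, and outside the list Tanc2 fell 4.08-fold. DESeq2 called 501 genes. The edgeR count of 184 was 65 without base library 2, 97 without base library 3 and 104 without base library 1. Areg lost its call without base libraries 1 or 2 (adjusted p = 0.0575 and 0.0795), Rgs2 without base library 2 (0.0753), and Nop16 without base library 3 (0.0595). Gata3 lost its call without base libraries 1, 2 or 3 (adjusted p = 0.152, 0.149 and 0.0739), CGRP library 3 (0.0568) or combined library 3 (0.05). The log2 change of Palld, 3.56, was 4.56 without base library 2.

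**Figure D4:**
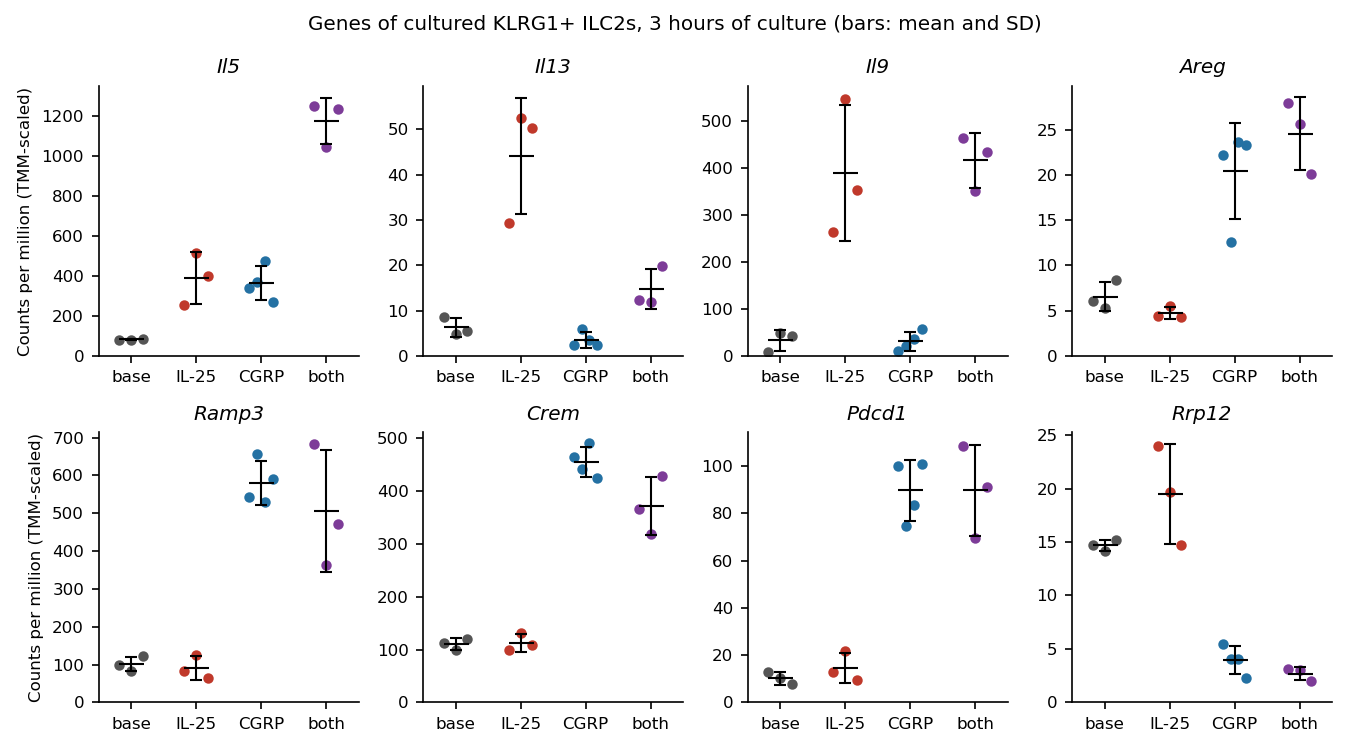
Level of 8 genes in cultured ILC2s (vertical axes, TMM-scaled CPM) in base medium, with IL-25, with CGRP and with both. Points are libraries, horizontal marks group means and error bars the SD over 3 or 4 libraries; Il5 lay at 82.1, 389, 363 and 1172, and Il13 at 6.30, 44, 3.54 and 14.8 in these groups.

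CGRP in the presence of IL-25 changed 78 genes against IL-25 alone, 62 higher and 16 lower (3 libraries each; DESeq2 296), to ask whether the neuropeptide acts alike on activated cells. Il5 rose further, from 389 ± 130 to 1172 ± 114 CPM (3.01-fold, adjusted p = 0.00346), and Areg rose 5.19-fold from 4.74 ± 0.706 CPM (adjusted p = 0.000519). Il13 stood at 44 ± 12.8 with IL-25 and 14.8 ± 4.45 CPM with both (log2 -1.57 ± 0.39, adjusted p = 0.0609, DESeq2 0.0101). Of 29 cAMP and immediate early genes 6 rose (18 adjusted over the list alone, camera adjusted p = 0.0554 with an estimated correlation). Among them were Crem at 3.29-fold, Dusp10 at 5.91-fold, Rgs2 at 3.90-fold and Fos at 5.39-fold. Outside the list Akap12 rose 6.95-fold. Ramp3 rose 5.55-fold from 91.3 ± 31.8 to 506 ± 162 CPM (adjusted p = 7.49e-05). Pdcd1 and Tnfrsf9, 2 of 18 costimulatory and inhibitory genes (4 adjusted over the list alone; adjusted p = 0.0646 with an estimated correlation), rose 6.17-fold and 3.10-fold. Of 20 ILC2 identity genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0986 with an estimated correlation), Hs3st1 by 4.48-fold and Il17rb by 2.10-fold, and Il2ra fell 2.22-fold. Gata3 stood at 402 ± 62.2 and 673 ± 184 CPM (adjusted p = 0.217, DESeq2 0.0423) and Calca at 681 ± 228 and 1469 ± 432 (adjusted p = 0.11, DESeq2 0.0184). Plaur, the urokinase receptor, rose 12.3-fold and the telomere protein gene Tinf2 6.42-fold, the actin gene Actc1 80.2-fold from 0.0625 CPM, and Palld had 2 and 202 counts (ratio 201, counting interval 55.0 to 1674).

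Ribosome biogenesis genes fell in 2 of 20 cases with CGRP and IL-25 (11 adjusted over the list alone, camera adjusted p = 0.054 with an estimated correlation), among them Rrp12 by 7.23-fold. Outside the list Nat10 fell 7.83-fold. Reln fell 25.8-fold to 0.364 ± 0.0999 CPM, and the epithelial transcripts Fabp1 and Fabp2, with 0 counts in the combined libraries, were at least 21.4-fold and 59.7-fold lower. Reln is known from endothelium and stood at 0.257 CPM in base medium and 9.37 with IL-25. Most other endothelial markers had lower means too, such as Lyve1 at 0.354 against 7.11 CPM (adjusted p = 0.0739), while Prox1 and Vwf were higher. Whether CGRP or other cells in the cultures caused these falls was not tested. The 57 genes called for CGRP both with and without IL-25 all changed in the same direction, where independent lists would share 0.737 in the same direction. The contrasts share no library but share the estimate of the spread, so the lists are not fully independent. Over all 12355 genes, most of them not called, the log2 changes of both contrasts correlated weakly (Pearson r = 0.196). The count of 78 was 38 without IL-25 library 1, 48 without combined library 3 and 208 without CGRP library 2. Fos lost its call without IL-25 library 1 (adjusted p = 0.0641), Reln without IL-25 library 1 or combined library 1 (0.16 and 0.0642), and Il2ra without IL-25 libraries 1 or 3 or combined libraries 1 or 3 (0.118, 0.0718, 0.105 and 0.154). Il17rb lost its call with no filter on low counts (adjusted p = 0.0619) and without base libraries 1 or 2 (0.0544 and 0.0547), IL-25 libraries 1, 2 or 3 (0.117, 0.0687 and 0.192) or combined libraries 1, 2 or 3 (0.122, 0.0544 and 0.126). Log2 changes were 3.55 for Fos without IL-25 library 3 and -3.97 for Nat10 without combined library 3, against 2.43 and -2.97 with all libraries, and Actc1 had 1 and 164 counts without IL-25 library 3 (ratio 155, counting interval 27.4 to 6160).

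IL-25 added to CGRP changed 14 genes against CGRP alone, 13 higher and 1 lower (3 and 4 libraries; DESeq2 41). Il9 rose from 30.7 ± 20.3 to 416 ± 58.4 CPM (13.6-fold, adjusted p = 0.000941), Il5 3.23-fold (adjusted p = 0.00331), Il13 4.18-fold from 3.54 ± 1.72 to 14.8 ± 4.45 CPM (adjusted p = 0.0127), Csf2 3.33-fold and Tph1 4.09-fold. Of 12 type 2 cytokines and ILC2 products 5 rose (7 adjusted over the list alone; adjusted p = 0.0291 with an estimated correlation). Camera's call of the NF-κB list, with 1 of 19 members higher (4 adjusted over the list alone), was lost (adjusted p = 0.159 with an estimated correlation). Ptgs2 rose 6.25-fold, Gadd45g 3.22-fold and Pim2 2.93-fold, and Eya2 fell 7.70-fold. Il5, Il9, Il13, Csf2, Pim2 and Ptgs2 were called for IL-25 both without and with CGRP, all higher in both, 6 genes where independent lists would share 0.00947 in the same direction. Both contrasts use the same estimate of the spread, so these lists are not fully independent. Over all 12355 genes, most of them not called, the log2 changes of both contrasts were close to uncorrelated (Pearson r = 0.0142). The count of 14 was 5 without combined library 3, 8 without CGRP library 1 or combined library 2, 9 without CGRP library 4 or combined library 1, and 27 without CGRP library 2. Ptgs2 lost its call without combined library 2 (adjusted p = 0.121), and Il13 with a fit on the compared groups alone (0.112) and without CGRP libraries 1 or 4 or combined library 3 (0.099, 0.0738 and 0.18). Csf2 lost it without CGRP libraries 1, 3 or 4 or combined libraries 1 or 3 (adjusted p = 0.106, 0.0911, 0.0967, 0.295 and 0.166), Pim2 without combined library 3 (0.0554) and Eya2 without combined libraries 1 or 3 (0.077 and 0.0866).

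The interaction contrast, which asks whether the CGRP response differs with IL-25, had 0 genes past 0.05 by edgeR and 0 by DESeq2, with 532 at an unadjusted p under 0.05 and 15 past 0.05 with no filter on low counts. The log2 difference between the CGRP responses of Il13 was -0.74 ± 0.53, and over the 17 genes named in every contrast it ran from -0.95 to 1.58 (lowest adjusted p = 0.9998). The ILC3 and ILC1 marker list was lower by camera (adjusted p = 0.0346), a call lost with adjusted p = 0.286 with an estimated correlation.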

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

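The test of tissue by condition and both tests of Hspa1a below were chosen only after the results were seen. Among 71 groups of 4 to 10 libraries or sums, 3 held a sample far from the others by Dixon's ratio, and chance alone gives about 1 in 20 such groups. Peyer's patch control library 7 had a median of 3975 UMIs per cell, where the group median was 3108. Peyer's patch control library 10 held 0.954% neutrophil-like cells against a group median of 0%. CGRP library 2 had 12.6 CPM of Areg against a group median of 22.8.

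The response of ILC2-like cells to food allergy differed between the lamina propria and Peyer's patches in 33 of 4465 genes by edgeR's test of tissue by condition, with a larger rise or smaller fall in the lamina propria for 26 and in Peyer's patches for 7 (418 at an unadjusted p under 0.05). The tissues also differ in run date and in the sort, so the difference cannot be given to the tissue alone. The log2 change in the lamina propria exceeded that in Peyer's patches by 6.95 for Hspa1a, 4.22 for Il5, 2.32 for Nr4a3, 2.29 for Pdcd1 and 0.95 for Cxcr6, and lay below it for Esm1 (-2.25) and Ppp1r15a (-1.04). For Hspa1a and Il5 the lamina propria controls held 1 and 5 UMIs, those of Il5 all in control library 3, so the size of these 2 differences is uncertain. Egr1 differed by 1.84, with log2 changes of 0.37 in the lamina propria and -1.44 in Peyer's patches. In the lamina propria IgDLow libraries, which enter no test, a cluster with T cell genes and Gata3, Il4, Il13, Il10 and Il17rb held 2.70% of food allergy cells (92 of 3409) and 0.077% of control cells (2 of 2598).

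Hspa1a was called higher in 7 of the 9 lamina propria classes in which it was tested, from lymphoid to myeloid cells. A single food allergy library does not account for this, since every food allergy library lay above every control library in 6 of the 7 classes, with plasma cells as the exception (lowest food allergy level 8.29 and highest control level 11.1 CPM), although food allergy library 3 was highest in all. A stress response to handling stays open: of 56 log2 changes of 8 immediate early genes in these classes 10 were called higher and 13 lower, with a lower quartile of -0.51, a median of -0.07 and an upper quartile of 0.39, and members that go both ways decide nothing. The copies Hspa1a and Hspa1b share sequence, so their UMIs cannot be parted with certainty. A heat shock response in the allergic tissue is a hypothesis that was not tested apart from handling.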

How the results depend on the processing

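The fits without Rn45s, edgeR's test of lamina propria shares without each library, and the fits without an unpartnered Peyer's patch control library and with clusters made without marker or list genes were chosen only after the results were seen. Of the named genes and receptor genes 1 changed direction: Calcrl in ILC2-like cells against the average log2 level of other classes, 1 of them at 0 UMIs, so that the fitted value is no fold. It was not past 0.05 and ran from log2 -0.61 without control library 2 (adjusted p = 1) to 1.05 without control library 1. The balance of Peyer's patch calls, 191 higher and 237 lower, turned to 37 and 32 with DESeq2 and 7 and 3 without the run date term. Without run date 4 or 5, 10 of 13 classes were left, and their 86 higher and 178 lower turned to 49 and 23 and to 60 and 20. With 25 cells per sum 8 classes were left, not including ILC2-like cells, and their 70 higher and 145 lower went to 96 and 270. Where the cause of a change is not given, the cause was not tested. DESeq2 called 24 genes for IL-25, 501 for CGRP, 296 for CGRP with IL-25, 41 for IL-25 with CGRP, 69 in Peyer's patches and 920 in the lamina propria, and 25 and 213 in their ILC2-like cells. With no filter on low counts, which tests more genes, the counts were 33, 328, 225 and 74 in the bulk contrasts, 15 for the interaction and 838 in Peyer's patches. A fit on the compared groups alone called 17 for IL-25 and 157 for CGRP with IL-25. Without the run date term the counts were 10 in Peyer's patches and 745 in the lamina propria, with 8 and 313 in ILC2-like cells, and Peyer's patch libraries taken each on its own gave 1243. EdgeR on cell counts put 2 class shares past 0.05 in Peyer's patches and 7 in the lamina propria (7 to 8 without each library). With an estimated correlation camera kept 5 of 23 list calls, and fry called 19 of the 120 list tests. The contrasts averaged over both bulk arms, chosen after the data were seen, called 31 genes for IL-25 (29 higher, 2 lower). For CGRP they called 658 (386 higher, 272 lower). Clusters made without marker or list genes gave 404 genes in Peyer's patches and 2067 in the lamina propria, over 11 and 8 classes, and 121 and 672 in ILC2-like cells.

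Leaving out 1 library or date gave 3 to 11 genes for IL-25, 65 to 215 for CGRP, 38 to 208 for CGRP with IL-25, 5 to 27 for IL-25 with CGRP, 72 to 545 in Peyer's patches, where 7 to 10 of the 13 classes were left and held 249 to 410 with all dates, 942 to 2892 in the lamina propria and 330 to 775 in its ILC2-like cells. Of 1204 such values of named genes past 0.05, 100 lost the call, and of 152 not past it 12 gained one. These values include fits without libraries outside the contrast, so the share lost per gene is larger. At least 1 such fit ended the call of 6 of 9 genes for IL-25 and 5 of 21 for CGRP. It did so for 4 of 20 for CGRP with IL-25 and 5 of 9 for IL-25 with CGRP. In the lamina propria these were 3 of 32 in ILC2-like, 2 of 12 in plasma cell-like and 3 of 13 in mast cell-like cells. In Peyer's patches they were 4 of 8 in ILC3-like and 2 of 5 in NK cell or ILC1-like cells. Under the other alternatives 78 of 1126 lost it and 14 of 97 gained it. With the replicate number as a block CGRP called 105 genes and IL-25 with CGRP 6. The numbers do not pair the libraries: 2 of 18 same-number pairs correlated over 0.1 (-0.14 to 0.128), and 4 of 12 libraries correlated best with their own number. The bulk simulations recovered few 2-fold changes, so depth and spread limit the bulk contrasts to large changes.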

Other observations

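The tests in this part were chosen after the results were seen, except the test of Mcpt1 in cells with at least 5 of its UMIs. The lamina propria IgDLow sort, with 1 library per condition, gave values that no test covers, with intervals for counting error only. Plasma cell-like cells made up 33% of the food allergy library and 18.4% of the control library, germinal centre B cell-like cells 5.05% and 0.385%, and mast cell-like cells 5.81% and 1.00%, while pDC-like cells were at 2.23% and 12.6% and cDC2-like cells at 1.41% and 4.39%. The plasma cell-like class was made up differently in each library. Cluster 24 was of low depth (median 796 UMIs) and led by immunoglobulin genes, with Ighg1 among them. It held 47.4% of the class in food allergy (533 cells) and 2.31% in the control (11 cells). Of all cells it made up 15.6% in food allergy and 0.423% in the control. The other clusters of the class, 6, 13 and 43, held 218, 330 and 43 of 3409 food allergy cells. In the control they held 160, 294 and 12 of 2598 cells, together no smaller a share. The higher plasma cell share thus lay in cluster 24, and the heavy chain levels cannot be parted from that cluster. Over the class Ighg1 was at 7113 CPM in food allergy and 322 in the control, 22.1-fold higher, and Ighe, the IgE heavy chain, had 373 UMIs and 0, at least 105-fold higher. Ighm was at 3224 and 1499 CPM and Ighg2b at 329 and 104, while Ighg2c was at 10.9 and 134, Ighg3 at 3.04 and 73.3, and Igha at 148900 and 128500. Mast cell genes were higher in the same cells, Mcpt1 23.1-fold and Cpa3 17.7-fold, and Ighg1 was also 30.3-fold higher in ILC3-like cells, at 228 against 7.53 CPM.

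In IgDLow ILC2-like cells Il13 was at 1686 CPM in food allergy and 71.9 in the control, Csf2 at 462 and 46.2, Ccl1 at 1279 and 246 and Hspa1a at 348 and 25.7. Macrophage-like cells held more of the monocyte-attracting chemokines Ccl7, 723 and 40.9 CPM, and Ccl2, 572 and 63.7 CPM, and 240 UMIs of Retnla, a gene of alternatively activated macrophages, against 2.

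Mast cell proteases rose with food allergy in lamina propria classes that should lack them. Doublets that the caller marked are argued against as the whole source, since with them removed Mcpt1 was past 0.05 in 5 of the 5 classes then tested, at log2 changes of 4.31 to 5.35. RNA of mast cells free in the suspension may be the source: in 10 of 11 classes Mcpt1 stood at a share of its mast cell level within 3-fold of the median share of the other mast cell genes, with monocyte-like cells at 3.08 as the exception. Unmarked doublets would also bring all mast cell genes at like shares, so these shares cannot part them from free RNA. Doublets that went unmarked stay open: 23.3% of the 1105 Mcpt1 UMIs outside mast cells lay in 3 cells with at least 5, between the bounds set beforehand, and of the 770 cells with any, 99.6% held under 5, as did 14.4% of mast cells (median 48), but droplets rich in mast cell RNA would have been named mast cells. No biological explanation, such as protease expression by the other cells, was tested.

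Mmrn1, Reln and Sdpr, known from endothelium, were among the 9 genes called for IL-25. Endothelial cells in the IL-25 cultures are a candidate explanation: the group means of 15 of 15 other endothelial markers were higher there than in base medium, among them Lyve1 at 7.11 against 0.15 CPM and Emcn at 2.63 against 0, although the KLRG1+ gate should have removed such cells. For 9 of the 15 every IL-25 library lay above every base library, which chance gives in 5% of cases, 3 had counts in 1 IL-25 library only, and 0 of the 7 tested passed 0.05 by edgeR against 5 at an unadjusted p under 0.05 and 2 by DESeq2. A response of the sorted cells to IL-25 stays open, with 0 of 3 of these genes called for IL-25 with CGRP (log2 changes of 0.84, 2.20 and 3.18) and none past 0.05 in the interaction contrast.

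Other splits of the samples into groups of the same sizes were tested in the same way. The CGRP count of 184 genes was reached by 1 of 35 splits, the real one, and the highest of the others called 19. A chance split of these libraries can thus be excluded there at 0.05, unadjusted for the other counts tested. This holds for libraries only, since the labels do not say whether they came from separate animals or cultures. For IL-25 with CGRP 2 of 35 splits called as many as the real 14, and the split of CGRP library 4 and combined libraries 1 and 3 from the rest called 52, which points to a structure of the samples that was not tested, so the splits do not exclude chance at 0.05 for that count. Of the 14 genes 6 were also called, in the same direction, for IL-25 without CGRP. That contrast shares no library but does share the estimate of the spread. In Peyer's patches the 16 splits that part the sums of every run date are too few for a share under 0.05: 3 of them called at least the real 428, and the highest other, which exchanged the conditions on dates 3, 4 and 5, called 572. Of 50 splits drawn from all, 44 left a date without a contrast between conditions and called up to 342. The splits were also too few for a share under 0.05 for IL-25 alone (9 genes, highest other 0, 10 splits), CGRP with IL-25 (78, highest other 1, 10 splits) and the lamina propria (2120, highest other 11, 10 splits). All 20 splits gave 0 genes for the interaction, as did the real one.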
